A study of Mus musculus with 16 samples.

How the data were processed

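Gene expression was measured on 1-colour microarrays of Affymetrix-type mouse probe sets in 16 samples of expanded blastocysts, 4 in each of 4 groups. Per the labels' protocols, each sample was a pool of 10 embryos, snap frozen before extraction with DNase treatment, and 5 embryo equivalents of total RNA were reverse transcribed, amplified by a linear isothermal method, fragmented and labelled with biotin. The groups, taken from the labels' group field, were blastocysts that developed in the mother (in vivo), blastocysts from in vitro fertilization grown in WM (IVF), and blastocysts made by intracytoplasmic sperm injection and grown in WM (ICSI-WM) or in KSOMaa (ICSI-KSOMaa).

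The deposited value table held linear intensity values for 45101 probe sets on the 16 arrays. The software, background correction and probe summary behind these intensities were not given in the sources used here. After 2% of values were trimmed at each end, the mean intensity of each array was 250.0, so the deposited arrays share a scale in this sense, but their medians were not matched. The dimmest values lay below 1. The number of arrays limits the precision. The labels do not say whether the pools of a group came from separate matings or days, so p-values measure the spread between these pools, part of which may be technical.

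Intensities below 1 were raised to 1 and log2 values were taken without further normalization. The platform annotation listed 34958 probe sets with 1 gene symbol, 932 with several and 9211 with none listed here. Symbols were updated through gene identifiers against the RefSeq gene table of GRCm38.p6, which matched 34754 of the 34958. No genome build was named for the values, so no coordinates are given. Each gene was represented by its probe set with the highest mean over the 16 arrays, which gave 18194 genes, and genes with a mean below the 25th percentile of all probe sets (an intensity of 8.51) were left out, leaving 14677. Some named genes, called or not, had other probe sets past this filter that moved the opposite way: for ICSI-WM against in vivo these were 1 of 2 for Cdx2, 1 of 3 for Gata6, 2 of 4 for Sod2 and 1 of 3 for Dnmt1, and for IVF against in vivo 1 of 3 for Zbtb38, 1 of 2 for Trp53inp1, 1 of 4 for Fgf4 and 1 of 2 for Cdx2. Between the media these were 1 of 3 for Gata6, 1 of 3 for Esrrb and 1 of 4 for Fgf4, and for ICSI-WM against IVF 1 of 2 for Txnip. Oxld1, Agap3, Aqp3, Slc2a3 and Dnmt3b had such a probe set in at least 1 comparison, and this list of genes is not complete.

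Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), in one model of the 4 group means over the 16 arrays that share one estimate of the spread, with Benjamini-Hochberg adjustment over the 14677 genes and a threshold of 0.05. The 5 comparisons were ICSI-WM, ICSI-KSOMaa and IVF against in vivo, ICSI-WM against IVF, and ICSI-WM against ICSI-KSOMaa. Changes are log2 differences with the standard error of the fit. The 36 gene lists fixed before the data were examined covered blastocyst lineages, stress and metabolic pathways, imprinting, the cell cycle and markers of other cells that a pool could carry; 870 of their 1028 members were measured. They were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 36 lists, and again with an estimated correlation and with fry, whose p asks whether a list moves one way on balance and does not compare it with other genes. A list needed 3 measured members. The median of each list called across the sets was also set against 10000 random lists matched on mean intensity in 50 bins. Single values per array were compared by two-sided exact permutation tests over 70 permutations, of which the smallest possible p is 0.0286.

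Named genes followed a rule fixed before the data were examined: per comparison the 8 highest and the 8 lowest changes among called genes whose groups did not overlap, up to 3 called members with the smallest p of each of at most 5 called lists, and 22 fixed genes of blastocyst biology, of which 18 were measured; Trp53, Bax, H19 and Ldlr were not analysed here. Where fewer than 5 genes passed, the 5 with the smallest p were named. Where a called list had no called member, the members given were chosen after their values were seen, and this is stated beside them.

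The fit was tested on simulated data with 200 changed genes among 14677. With noise as in IVF and in vivo, it recovered 7% of genes changed by 1 on the log2 scale and 50% of those changed by 2, with 8 false calls. For ICSI-WM against ICSI-KSOMaa it recovered 3% and 46%, with 1 false call, and for ICSI-WM against in vivo 8% and 57%, with 5 false calls. No 2 arrays of a group held identical values, and no array was left out of the fit. Alternatives were quantile normalization, centring each array on its median, no filter on dim genes, a filter at the 50th percentile (an intensity of 24.4), the mean of a gene's probe sets, probe sets tested singly, the 8 arrays of a comparison alone, the replicate number as a block, array weights, a variance trend with robust estimation, a floor of 16, and each array left out in turn. Leaving out 3 arrays with high 3' to 5' ratios together, joining quantile normalization with the stricter filter, and some of these settings for the gene lists were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.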

Results

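Expanded mouse blastocysts were profiled on 16 arrays in 4 groups of 4 pools. In the in vivo group, embryos developed in the mother. In the IVF group, oocytes were fertilized in a dish and grown in the medium that the labels call WM. In the ICSI groups, a sperm was injected into each oocyte and embryos were grown in WM or in a medium called KSOMaa. The study asked how ICSI changes gene expression of preimplantation embryos, and the groups separate the way of fertilization, culture and the medium as far as the arrays allow.

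The arrays fell into 2 sets of 8. The median intensity of all probe sets was 18.9 to 22.2 on the 8 ICSI arrays and 36.4 to 75.4 on the 8 in vivo and IVF arrays, although their trimmed means were the same. Bacterial hybridisation controls, which come from no embryo, differed between the sets as well: for all 9 control probe sets every in vivo and IVF array was brighter than every ICSI array, by 1.12 on the log2 scale on average. The first principal component, 47.1% of the variance of 14677 genes, separated the same sets. Correlations between arrays were 0.84 to 0.94 within a set and 0.75 to 0.87 between sets. Comparisons of an ICSI group with in vivo or IVF embryos therefore cross the sets, and there batch and group cannot be told apart. IVF against in vivo, and ICSI-WM against ICSI-KSOMaa, lie within a set. The log2 ratio of the 3' to the 5' probe set of Gapdh, a sign of RNA quality, was 1.14 ± 0.54 (SD, n = 4) in vivo, 1.03 ± 0.08 in IVF, 1.04 ± 0.20 in ICSI-WM and 1.07 ± 0.19 in ICSI-KSOMaa embryos, and no comparison of it or of b-actin passed an exact permutation test (lowest p = 0.143).

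**Figure D1:**
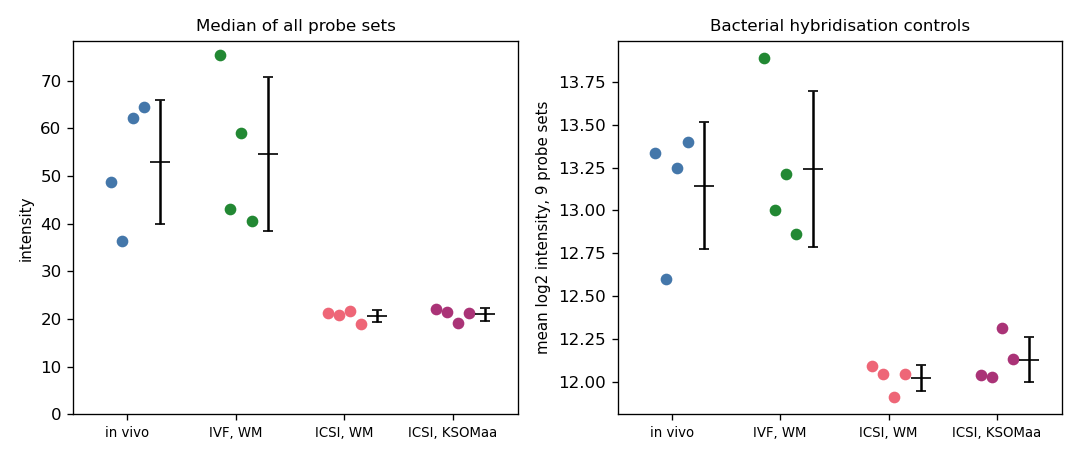
Median intensity of all probe sets (left) and mean log2 intensity of 9 bacterial hybridisation control probe sets (right) on each array. Points are arrays, the black marks are means with 1 SD (n = 4), and ICSI medians of 18.9 to 22.2 lie below in vivo and IVF medians of 36.4 to 75.4.

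IVF embryos grown in WM differed from in vivo embryos in genes that respond to p53. Ccng1, a cyclin induced by p53, rose by 2.29 ± 0.21 on the log2 scale (SE, n = 4 per group), from an intensity of 1170 to 5700 (limma adjusted p = 0.00053). Cdkn1a, the cell cycle inhibitor p21, rose by 2.26 ± 0.35 from 80.0 to 383 (adjusted p = 0.0187). Trp53inp1 rose by 1.27 ± 0.18 (adjusted p = 0.0117), although the mean of its probe sets gave 0.58 (adjusted p = 0.711). Of 23 measured p53 targets, 22 had a positive change, 3 passed over all genes and 12 adjusted over the list alone, and the list rose with a median of 0.88 (camera adjusted p = 2.78e-12, and adjusted p = 0.0207 with an estimated correlation). The mean of the list was 8.86 ± 0.10 (SD, n = 4) in IVF and 7.85 ± 0.17 in vivo, with no overlap of arrays.

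The largest rise of IVF embryos was in Txnip, which codes for a protein that binds thioredoxin and restrains glucose uptake. Its intensity was 38.5 in vivo and 1070 in IVF, a log2 change of 4.80 ± 0.71 (limma adjusted p = 0.0123). Slc16a6, a monocarboxylate transporter family member, rose by 2.62 ± 0.35, Ephx1, an epoxide hydrolase, by 2.63 ± 0.45, Zfp688 by 2.90 ± 0.42, Drc1 by 2.79 ± 0.47, Trim35 by 2.74 ± 0.49 and Zbtb38 by 2.48 ± 0.34. The fall was steepest for Socs3, a feedback inhibitor of cytokine signalling through STAT3, which went from 2150 to 151, a change of -3.83 ± 0.52 (adjusted p = 0.00754). Ssbp4 changed by -3.75 ± 0.58, C030006K11Rik by -2.66 ± 0.46, Lrrc20 by -2.64 ± 0.34, Snhg3 by -1.87 ± 0.33 and Mettl17 by -1.35 ± 0.25. All 6 falling genes had IVF arrays below every in vivo array. Calls of 7 of these genes were lost when 1 array was left out: Drc1 without in vivo replicate 1 or IVF replicate 2 or 4 (adjusted p up to 0.0828), Trim35 without in vivo replicate 1 or any IVF array (up to 0.0987), Ephx1 without in vivo replicate 2 or IVF replicate 2, 3 or 4 (up to 0.0887) and Ssbp4 without IVF replicate 2 or 3 (up to 0.0654). The same held for C030006K11Rik without in vivo replicate 2 or 3 or IVF replicate 1, 2 or 4 (up to 0.0887), Snhg3 without in vivo replicate 1 or 2 or IVF replicate 1, 2 or 3 (up to 0.0947) and Mettl17 without any array but in vivo replicate 4 (up to 0.103). By the mean of their probe sets Trim35 (0.85, adjusted p = 0.531), Zbtb38 (0.92, 0.455), C030006K11Rik (-1.79, 0.427) and Mettl17 (-1.01, 0.11) did not pass, nor did Drc1 with a floor of 16 (1.27, 0.211). With that floor the falls of Ssbp4, C030006K11Rik and Lrrc20 were smaller, at -2.17, -1.61 and -1.36, and still passed (adjusted p = 0.00369, 0.0325 and 0.0462).

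**Figure D2:**
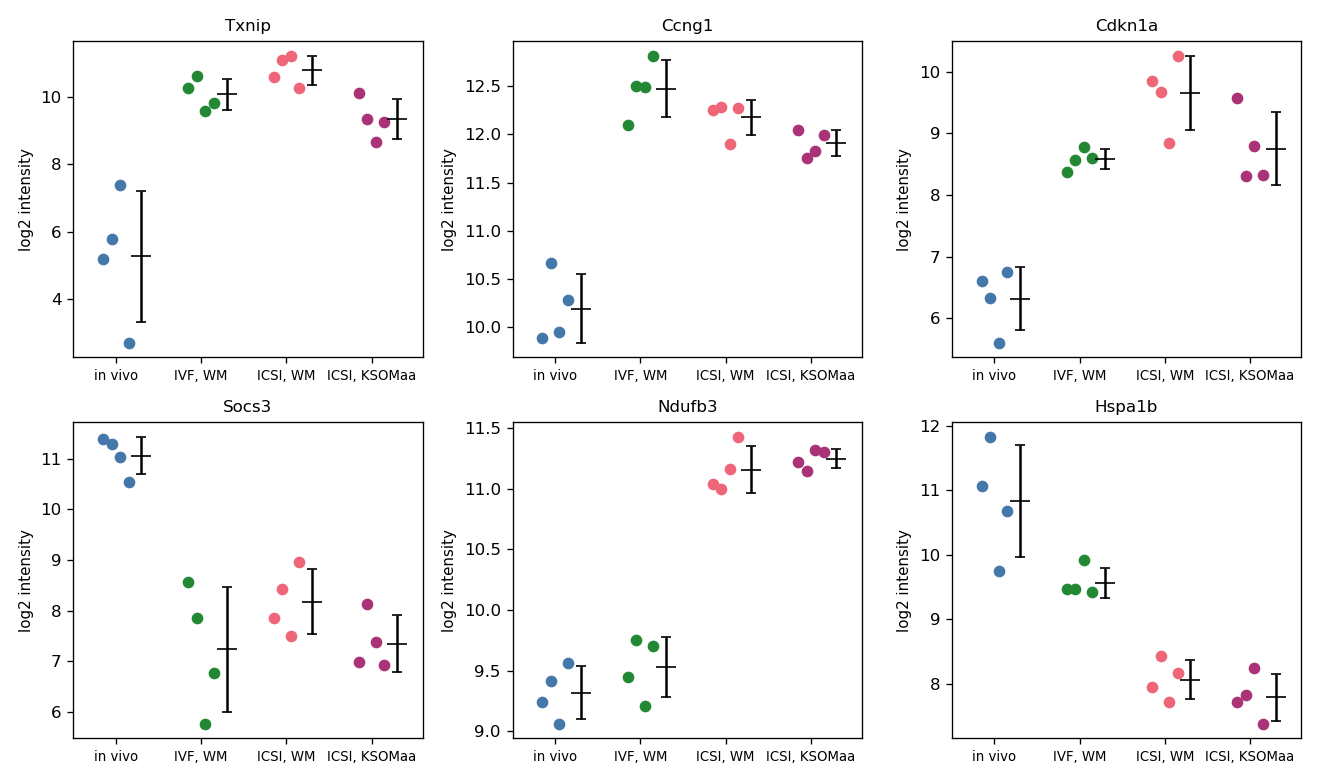
Log2 intensity of 6 named genes on each array, where points are arrays and black marks are means with 1 SD (n = 4). Txnip, Ccng1 and Cdkn1a were lowest in vivo and Socs3 highest, while Ndufb3 was higher on the ICSI arrays (intensities of 2280 and 2430) than in vivo (638).

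Lists of inner cell mass genes were lower in IVF than in vivo embryos. The epiblast and pluripotency list fell with a median of -0.34 (camera adjusted p = 0.000211, and adjusted p = 0.0349 with an estimated correlation). No member of its 25 passed over all genes, while 5 passed as lower and 1 as higher adjusted over the list alone. Members chosen after their values were seen were Fgf4, a growth factor of the epiblast, at -1.44 ± 0.30 (adjusted p = 0.0689), Tdgf1 at -0.96 ± 0.21 and Nr0b1 at -3.32 ± 0.76. Dppa4, chosen in the same way, went the other way at 0.59. The core factors Nanog (0.11 ± 0.17, adjusted p = 0.885) and Pou5f1 (0.17 ± 0.29, adjusted p = 0.905) did not pass. The primitive endoderm list fell with a median of -0.56 over 21 members (camera adjusted p = 0.000718, but adjusted p = 0.517 with an estimated correlation). Its members chosen after their values were seen were Lamc1 at -1.12 ± 0.32, Gata4 at -2.05 ± 0.74 and Sox17 at -1.12 ± 0.47, and Gata6, a fixed gene and a main factor of this lineage, was at 0.01 ± 0.18 (adjusted p = 0.994), none past the threshold over all genes or adjusted over the list alone. Without IVF replicate 3 Gata4 was at -1.18 and Sox17 at -0.57, and Gata4 was at -0.93 by the mean of its probe sets. Without in vivo replicate 1, where Gata4 was high, it was at -1.78. For the trophectoderm, Cdx2 changed by 0.06 ± 0.16 (adjusted p = 0.951) and Krt8 by 0.38 ± 0.24.

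Genes of amino acid supply were also lower as lists in IVF embryos. The amino acid response list of ATF4 targets had a median of -0.25 with 26 of 33 members negative (camera adjusted p = 0.00743, but adjusted p = 0.604 with an estimated correlation). Amino acid transporters had a median of -0.38 over 22 members (camera adjusted p = 0.00972, adjusted p = 0.604 with an estimated correlation). Atf4 itself was at -0.84 ± 0.23 (adjusted p = 0.157) and Slc7a1, an arginine and lysine transporter, at -0.93 ± 0.28 (adjusted p = 0.218), both chosen after their values were seen. Others chosen in this way were Nupr1 at -3.19, Slc7a7 at -1.28 and Slc7a3 at -1.40. Ddit4 at 1.76 and Slc38a1 at 0.67, also chosen in this way, went the other way. No member of either list passed over all genes; adjusted over the list alone, 1 ATF4 target was higher and 3 lower, and 3 transporters were lower. The ATF4 call was lost without in vivo replicate 2 (adjusted p = 0.0612), and the transporter call without in vivo replicate 1 (0.176) or 2 (0.113) or IVF replicate 1 (0.0845). Asns was at -0.76 ± 0.35 and Hspa1b, a heat shock protein, at -1.26 ± 0.36, neither past the threshold.

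In total 20 genes were higher and 6 lower in IVF than in vivo embryos (limma, adjusted p under the threshold of 0.05), and 1554 had an unadjusted p under 0.05. These calls used the spread of all 16 arrays; with the 8 arrays of the comparison alone, whose own spread is wider, no gene passed (923 at an unadjusted p under 0.05), while the p53 list stayed past the threshold (camera adjusted p = 1.69e-11). Leaving out in vivo replicate 4, which had the highest Gapdh 3' to 5' ratio, raised the counts to 78 and 53. Without in vivo replicate 2 or 3, 32 and 36 genes were higher, and without IVF replicate 2 or 3, 10 and 13. Cdkn1a missed the threshold without either of these IVF arrays (adjusted p = 0.055 and 0.052), and Ccng1, Cdkn1a and Trp53inp1 missed it after centring on the median (adjusted p = 0.0704, 0.137 and 0.276), where their changes were 2.25, 2.23 and 1.23. The share of calls that were higher, 76.9%, became 60% after quantile normalization and 33.3% after centring, where 1 gene was higher and 2 lower.

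ICSI embryos grown in WM differed from in vivo embryos in mitochondrial genes and in p53 targets, across the sets of arrays. Of 71 measured genes of oxidative phosphorylation, 46 rose and 6 fell, or 49 and 6 adjusted over the list alone, with a list median of 0.94 (camera adjusted p = 3.19e-12, but adjusted p = 0.466 with an estimated correlation). Ndufb3, a complex I subunit, rose by 1.84 ± 0.18 from 638 to 2280, Atp5l by 1.64 ± 0.18 and Uqcr10 by 1.61 ± 0.18. Of 23 p53 targets 13 rose and none fell, and 15 rose adjusted over the list alone (median 0.76, camera adjusted p = 0.000163, adjusted p = 0.466 with an estimated correlation). Cdkn1a rose by 3.33 ± 0.35, Phlda3 by 3.52 ± 0.47 and Ccng1 by 1.99 ± 0.21. Of 21 genes of the apoptosis machinery 8 rose and 2 fell, as they did adjusted over the list alone (median 0.57, camera adjusted p = 0.0462, adjusted p = 0.466 with an estimated correlation). Casp2 rose by 1.64 ± 0.24 and Aifm1 by 1.04 ± 0.22, and Casp8 changed by -2.35 ± 0.45, or by -0.77 after quantile normalization, where it did not pass (adjusted p = 0.189).

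Txnip had the largest rise in this comparison too, from 38.5 to 1750 (5.51 ± 0.71, limma adjusted p = 0.000166). Oxld1 rose by 5.13 ± 0.65, Mical1 by 4.86 ± 1.02, Tepsin by 4.68 ± 0.48, Ccdc28b by 4.68 ± 0.87, Ticam1 by 4.62 ± 0.38, S100a6 by 4.58 ± 0.49 and Cd81, a tetraspanin, from 94.7 to 2190. The 8 steepest falls were Gm3715, Mup10, Gm26611, Vmn2r84, Serpinb5, Adam4, Acvr1c and Myocd. Their mean intensities were 163 to 1170 in vivo and 1.03 to 2.70 in ICSI-WM, at or near the floor of 1, so their changes of -9.63 to -6.72 depend on that floor and were -6.19 to -3.35 with a floor of 16. With that floor the rises of Oxld1, Mical1, Tepsin, Ccdc28b and Ticam1 were 3.39, 3.53, 2.39, 2.47 and 2.03. Among the fixed genes, Pou5f1 rose by 1.29 ± 0.29, Gata6 by 0.85 ± 0.18, Sod2 by 1.09 ± 0.23, Igf2 by 1.94 ± 0.57 and Asns, asparagine synthetase, by 1.68 ± 0.35. Hspa1b changed by -2.76 ± 0.36 (adjusted p = 0.000166). Cdx2 (-0.81 ± 0.16), Nanog (-1.15 ± 0.17), Slc2a3 (-0.77 ± 0.21), Dnmt3b (-0.83 ± 0.20) and Dnmt1 (-0.46 ± 0.16) were lower, but turned positive when each array was centred on its median, with 0.52, 0.17, 0.56, 0.50 and 0.86. By the mean of their probe sets Gata6 (0.22, adjusted p = 0.444), Sod2 (0.20, 0.491), Igf2 (0.39, 0.536), Cdx2 (-0.31, 0.288), Dnmt3b (-0.47, 0.16), Dnmt1 (-0.07, 0.822) and Slc2a3 (-1.01, 0.0539) did not pass. After quantile normalization Cdx2 (-0.03, 0.89), Slc2a3 (-0.19, 0.481), Dnmt1 (-0.39, 0.0943) and Igf2 (2.14, 0.0678) did not pass, and Igf2 and Dnmt1 did not with the 8 arrays alone (0.0751 and 0.106). The call of Dnmt1 was also lost without any of ICSI-WM replicates 1, 2 and 3 and in vivo replicates 1, 3 and 4 (0.0641 to 0.0999).

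In total 2362 genes were higher and 2876 lower in ICSI-WM than in vivo embryos. Of the lower genes 54.3% lay below the median intensity of all probe sets, against 2.41% of the higher genes. The share of calls that were higher was 45.1%, and became 63.7% after quantile normalization and 89.9% after centring on the median. The median change of all genes was -0.12, and 0.19 and 1.20 under these settings. The median of oxidative phosphorylation, 0.94, compares with -0.07 for random lists of the same intensities. The median of the apoptosis list, 0.57, lay within the central 95% of its random lists, -0.24 to 0.66. The apoptosis list lost its call after quantile normalization (adjusted p = 0.144), without ICSI-WM replicate 3 (adjusted p = 0.057) and without in vivo replicate 4 (adjusted p = 0.0843). Lists of markers of other cells did not pass with camera in this comparison. With fry, which called 19 lists, 3 of the marker lists were lower. Leukocyte and red blood cell markers (median -0.41, fry adjusted p = 0.892) were not. Cumulus and granulosa cell markers had a median of -0.91 (4 of 12 lower, camera adjusted p = 0.125, fry adjusted p = 0.00197), oviduct and uterine epithelium markers -0.88 (5 of 13 lower and 1 higher, 0.186 and 0.00742) and sperm and spermatid transcripts -1.51 (5 of 11 lower, 0.0648 and 0.00074). With an estimated correlation these 3 lower lists had camera adjusted p = 0.485, 0.485 and 0.466.

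ICSI embryos grown in KSOMaa were also compared with in vivo embryos across the sets of arrays. Of 71 oxidative phosphorylation genes 49 rose and 5 fell (median 1.08, camera adjusted p = 2.79e-14, but adjusted p = 0.363 with an estimated correlation), with Ndufb3 at 1.93 ± 0.18. Of 23 p53 targets 11 rose (median 0.85, camera adjusted p = 0.000985, adjusted p = 0.363 with an estimated correlation), with Ccng1 at 1.72 ± 0.21, Cdkn1a at 2.43 ± 0.35 and Phlda3 at 3.19 ± 0.47. Of 33 ATF4 targets 12 rose and 1 fell (median 0.65, camera adjusted p = 0.00372, adjusted p = 0.363 with an estimated correlation): Aars and Sars, which load alanine and serine on their transfer RNAs, rose by 2.11 ± 0.29 and 2.05 ± 0.30, and Slc3a2, the shared chain of several amino acid transporters, by 1.53 ± 0.27. Of 23 fatty acid oxidation genes 13 rose and 4 fell (median 0.85, camera adjusted p = 0.0166, adjusted p = 0.363 with an estimated correlation), with Etfb at 1.83 ± 0.27 and Acaa2 at 1.5 ± 0.25. The apoptosis machinery (median 0.52, 6 of 21 up and 1 down), the TCA cycle (median 0.41, 10 of 24 up and 3 down) and cholesterol biosynthesis (median 0.83, 7 of 20 up and 3 down) passed as higher, but not with an estimated correlation (adjusted p = 0.363, 0.363 and 0.543). Sperm and spermatid transcripts passed as lower, with 4 of 11 called and a median of -1.23 and a mean log2 intensity of 2.92 ± 0.30 (SD, n = 4) in ICSI-KSOMaa and 4.79 ± 0.63 in vivo, but not with an estimated correlation (adjusted p = 0.363). The sperm list fell less than most random lists of the same intensities, whose median was -1.79 with a central 95% of -2.92 to -0.58, and apoptosis (0.52, against -0.25 to 0.66) and the TCA cycle (0.406, against -0.281 to 0.408) also lay within that range of their random lists. The camera adjusted p was 0.0246 for apoptosis, 0.0257 for the TCA cycle, 0.039 for cholesterol biosynthesis and 0.0468 for sperm transcripts. Adjusted over the list alone, 49 genes of oxidative phosphorylation rose and 6 fell, and 13 p53 targets, 12 ATF4 targets, 15 genes of fatty acid oxidation, 6 of apoptosis, 11 of the TCA cycle and 8 of cholesterol biosynthesis rose. After quantile normalization 3 of these 8 lists passed, together with the ribosomal proteins, which had not passed before, and those of fatty acid oxidation (adjusted p = 0.0856), the TCA cycle (0.12), apoptosis (0.12), cholesterol biosynthesis (0.227) and sperm transcripts (0.327) did not. Calls were also lost when 1 array was left out: the TCA cycle without in vivo replicate 3 (0.0708), apoptosis without in vivo replicate 4 (0.0745), cholesterol biosynthesis without in vivo replicate 4 (0.0805) or ICSI-KSOMaa replicate 1 (0.0585) or 3 (0.0769), and sperm transcripts without any of ICSI-KSOMaa replicates 1, 2 and 3 and in vivo replicates 1, 3 and 4 (0.0579 to 0.0805). Among other lists of markers of other cells, cumulus and granulosa cell markers (median -1.70, camera adjusted p = 0.0945, fry adjusted p = 0.00101) and oviduct and uterine epithelium markers (-1.66, 0.122 and 0.00319) were lower with fry alone. Leukocyte and red blood cell markers were not (-0.25, 0.658 and 0.448). With an estimated correlation the cumulus and oviduct lists each had a camera adjusted p of 0.363, and fry does not compare a list with other genes.

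Among single genes, Ccdc28b (5.33 ± 0.87), Ticam1, Oxld1, Cox6b2, Cd81, Mical1, Tceal9 and Tepsin (4.65 ± 0.48) rose most, and the steepest falls were of genes whose ICSI-KSOMaa means were 1 to 2.43, at or near the floor, from Gm3715 (-10.15 ± 0.70) and Mup10 to an immunoglobulin kappa variable gene (-6.82 ± 0.82). These changes depend on the floor of 1: with a floor of 16, Gm3715 was at -6.19 and the immunoglobulin gene at -3.66, and Ccdc28b, Ticam1, Oxld1, Mical1 and Tepsin at 3.12, 2.32, 3.14, 3.33 and 2.36. Txnip rose by 4.07 ± 0.71, Asns by 1.95 ± 0.35, Gata6 by 1.27 ± 0.18, Krt8 by 0.88 ± 0.24 and Aqp3, a water and glycerol channel, by 0.87 ± 0.31. The call of Aqp3 was lost by the mean of its probe sets (0.18, adjusted p = 0.69), after quantile normalization (0.67, 0.139) and without any of ICSI-KSOMaa replicates 1, 2 and 4 and in vivo replicates 1, 2 and 4 (0.0601 to 0.103). Gata6 was lost by the mean of its probe sets (0.45, 0.117) and Krt8 with the 8 arrays alone (0.0602). Hspa1b changed by -3.04 ± 0.36. Cdx2, Nanog, Slc2a3, Igf2r and Dnmt3b were lower by the scale used (-0.65, -1.03, -0.67, -0.52 and -0.59) and positive after centring on the median (0.65, 0.27, 0.63, 0.79 and 0.71), and Dnmt3b was at 0.04 by the mean of its probe sets. By that mean Cdx2 (-0.13, adjusted p = 0.67), Slc2a3 (-0.81, 0.11) and Igf2r (-0.51, 0.0695) did not pass, and after quantile normalization Cdx2 (-0.06, 0.803), Slc2a3 (-0.21, 0.432) and Dnmt3b (-0.42, 0.13) did not. Calls were lost for Slc2a3 without ICSI-KSOMaa replicate 2 or in vivo replicate 1 or 3 (up to 0.062), Igf2r without ICSI-KSOMaa replicate 1 or 3 or in vivo replicate 1, 2 or 3 (up to 0.0698) and Dnmt3b without any of replicates 1, 2 and 3 of both groups (up to 0.0907). In total 2437 genes were higher and 3063 lower (limma), 44.3% of them higher, a share that became 62.2% after quantile normalization and 88.6% after centring.

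ICSI-WM against IVF asked about the way of fertilization in the same medium, and crossed the sets of arrays. Oxidative phosphorylation was again higher in ICSI embryos, with 40 of 71 genes up and 6 down, or 45 and 6 adjusted over the list alone (median 0.90, camera adjusted p = 1.18e-11, but adjusted p = 0.524 with an estimated correlation). Ndufb3 rose by 1.63 ± 0.18, Uqcr11 by 1.71 ± 0.20 and Ndufb8 by 1.79 ± 0.21. Asns rose by 2.44 ± 0.35, Aqp3 by 1.49 ± 0.31 and Cdkn1a by 1.07 ± 0.35, while Txnip, at 0.71 ± 0.71, did not pass (adjusted p = 0.466). The list of p53 targets did not pass (median 0.06, camera adjusted p = 0.693). Of its 23 members 13 had a positive and 10 a negative change, and 3 rose and 1 fell over all genes. The call of Cdkn1a was lost after quantile normalization (0.82, adjusted p = 0.205) and without any of ICSI-WM replicates 1, 2 and 4 and IVF replicates 1, 2 and 4 (0.054 to 0.0979). By the mean of their probe sets Aqp3 (0.72, adjusted p = 0.102), Ndufb8 (1.25, 0.0965) and Agap3 (1.06, 0.163) did not pass. The largest rises were of Ticam1 (5.13 ± 0.38), Lhpp, Ring1, S1pr5, Shf, Abtb1, Gpa33 and Agap3 (3.68 ± 1.02), and the largest falls of Gm3715 (-9.32 ± 0.70), Mup10, Gm26611, Vmn2r84, Serpinb5, Selp, 6430553K19Rik and Tmem86b (-6.72 ± 1.14), whose ICSI-WM means were 1 to 2.70, at or near the floor of 1. These changes depend on that floor: with a floor of 16, Gm3715 was at -5.88, Selp at -3.40, Tmem86b at -3.54, Ticam1 at 2.03 and Agap3 at 2.25. Hspa1b changed by -1.5 ± 0.36, but by -0.14 after centring on the median (adjusted p = 0.811) and by -0.92 by the mean of its probe sets (0.171). Cdx2 (-0.86 ± 0.16), Nanog (-1.26 ± 0.17), Slc2a3 (-0.72 ± 0.21), Dnmt1 (-0.53 ± 0.16) and Dnmt3b (-0.67 ± 0.20) were lower, but positive after centring on the median, with 0.50, 0.09, 0.64, 0.83 and 0.68. By the mean of their probe sets Cdx2 was at 0.03 and Dnmt1 at 0.17, and Igf2, which rose by 1.77 ± 0.57, was at -0.67. By that mean Dnmt3b (-0.30, adjusted p = 0.373) and Slc2a3 (-0.43, 0.411) did not pass, and after quantile normalization Cdx2 (-0.04, 0.857), Slc2a3 (-0.12, 0.687), Dnmt3b (-0.50, 0.0874), Dnmt1 (-0.46, 0.0577) and Igf2 (2.10, 0.0805) did not. Calls were lost for Igf2 without any of ICSI-WM replicates 1, 2 and 3 and IVF replicates 1, 3 and 4 (up to 0.0701), Dnmt1 without ICSI-WM replicate 2 or 3 or IVF replicate 1 or 2 (up to 0.0649), Dnmt3b without ICSI-WM replicate 1 or 4 or IVF replicate 1 (up to 0.0618) and Slc2a3 without IVF replicate 3 (0.053). Lists of markers of other cells did not pass with camera, but were lower with fry. Medians were -1.01 for cumulus and granulosa cells (fry adjusted p = 0.00252), -1.52 for oviduct and uterine epithelium (0.00192), -0.80 for leukocytes and red blood cells (0.0389) and -1.40 for sperm (0.00128). With an estimated correlation their camera adjusted p was 0.524, 0.524, 0.711 and 0.524. Fry does not compare a list with other genes, and 55.4% of all genes lower in ICSI-WM than IVF lay below the median intensity. Fewer such cells in the ICSI-WM pools cannot be read from these lists. In total 1954 genes were higher and 2738 lower, 41.6% of them higher against 63.3% after quantile normalization and 90% after centring.

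Medium was compared in ICSI embryos, within a set of arrays. The amino acid response list was lower in WM: 31 of 33 ATF4 targets had a negative change, with a median of -0.38 (camera adjusted p = 3.68e-10, but adjusted p = 0.144 with an estimated correlation). No member of this list passed over all genes or adjusted over the list alone; those chosen after their values were seen were Trib3 at -1.69 ± 0.51, Stc2 at -1.48 ± 0.46, Mthfd2, a mitochondrial folate enzyme, at -1.19 ± 0.38 and Chac1 at -2.04 ± 0.76. Trib3 was at -1.12 without ICSI-WM replicate 3, Chac1 at -1.35 without ICSI-WM replicate 2 and Stc2 at -0.73 with a floor of 16. The mean of the list was 8.26 ± 0.34 (SD, n = 4) in WM and 8.88 ± 0.25 in KSOMaa, with overlapping arrays. Primitive endoderm genes were lower in WM with a median of -0.54 over 21 members (camera adjusted p = 2.91e-07, adjusted p = 0.144 with an estimated correlation), and epiblast genes with a median of -0.26, 23 of 25 negative (camera adjusted p = 6.89e-05, adjusted p = 0.0546 with an estimated correlation). Sox17 (-1.14 ± 0.47), Col4a2 (-0.75 ± 0.32), Fgf4 (-0.64 ± 0.30) and Esrrb (-0.54 ± 0.26), chosen after their values were seen, did not pass, and Esrrb was at -0.05 by the mean of its probe sets. Among the fixed genes Gata6 was at -0.42 ± 0.18, Nanog at -0.11 ± 0.17 and Pou5f1 at -0.02 ± 0.29 (adjusted p = 1 for each). Ribosomal proteins (median -0.17 over 42) and oxidative phosphorylation (median -0.10 over 71) passed as lower with camera (adjusted p = 0.000238 and 0.0154), but not with an estimated correlation (adjusted p = 0.754 and 0.773) nor after quantile normalization (adjusted p = 0.687 and 0.151). Without ICSI-KSOMaa replicate 3 both missed the threshold (adjusted p = 0.0574 and 0.335), and oxidative phosphorylation also did without ICSI-KSOMaa replicate 4 (0.0616) or ICSI-WM replicate 1 (0.082) or 2 (0.137).

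No single gene passed between the media (limma, smallest adjusted p = 0.0728), and 567 had an unadjusted p under 0.05. The smallest p values belonged to 8030442B05Rik, Fgr, Batf2, Itgb8 and Gm28453, with group mean intensities of at most 18.9, so none is given as changed. Txnip was at 1.44 ± 0.71 and Cdkn1a at 0.90 ± 0.35. Few changes of moderate size could be seen with these pools, since in simulated data 3% of genes changed by 1 on the log2 scale were recovered.

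**Figure D3:**
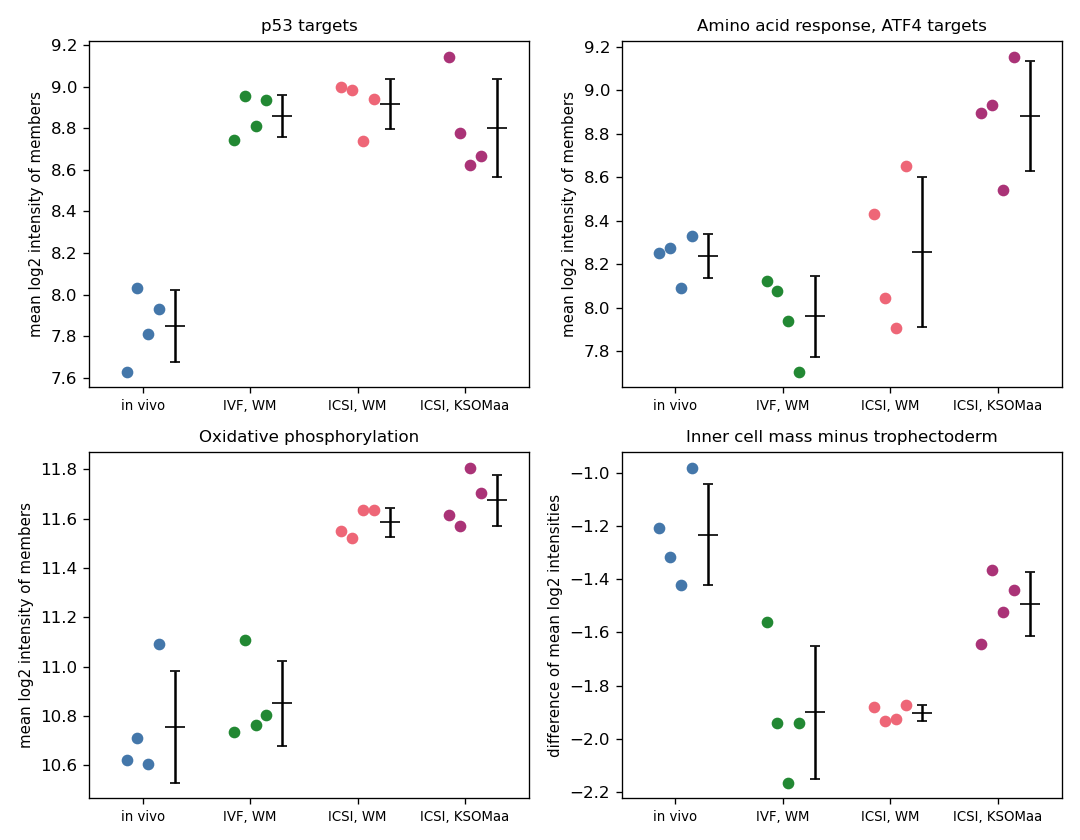
Mean log2 intensity of the members of 3 lists on each array, and the mean of inner cell mass genes minus that of trophectoderm genes (lower right). Points are arrays and black marks are means with 1 SD (n = 4); p53 targets were 7.85 in vivo on average against 8.86 in IVF, and oxidative phosphorylation followed the sets of arrays.

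Comparisons that share arrays were set against chance. ICSI-WM and ICSI-KSOMaa shared 2048 higher and 2325 lower genes against in vivo, where independent lists would share 392 and 600, and simulated unchanged groups against the same controls shared 1.99 on average. Their changes correlated across genes, which are not independent replicates, at r = 0.93 (0.59 in simulated unchanged groups), with a covariance of 2.26 against 0.247. With the in vivo arrays split into 2 and 2, r was 0.75 to 0.77 and 2101 to 2178 genes were shared. Both comparisons hold the same difference between sets of arrays. ICSI-WM and IVF shared 19 of the 20 genes higher and 4 of the 6 lower in IVF than in vivo, where independent lists would share 3.22 and 1.18 and simulated unchanged groups 2.40. The correlation of their changes was 0.30, against 0.55 in simulated unchanged groups, and the covariance was 0.327 against 0.247. The simulated groups held noise only, while ICSI-WM against in vivo also held the difference between the sets of arrays. An r below the simulated one therefore does not show that the changes were less alike than by chance. With split in vivo arrays r was -0.10 to 0.24 and 15 to 31 genes were shared. ICSI-KSOMaa and IVF shared 18 and 4 genes (3.32 and 1.25 for independent lists), with r = 0.28 against a simulated 0.55 and a covariance of 0.308 against 0.247. With split in vivo arrays their r was -0.11 to 0.22 and 14 to 32 genes were shared. The fertilization and medium comparisons, which share the ICSI-WM arrays, shared 0 genes because the second called none (567 at an unadjusted p under 0.05), with r = 0.14 against a simulated 0.46. The limit given for r of ICSI-WM and IVF holds for this r and for that of ICSI-KSOMaa and IVF.

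Sex-linked genes were read because the share of male embryos can differ between pools. Xist, expressed from the inactive X chromosome, did not pass in any of the 5 comparisons (lowest adjusted p = 0.436). Of the Y-linked genes Eif2s3y, Kdm5d and Uty, Uty was lower in ICSI-KSOMaa than in vivo embryos (-2.01 ± 0.62, adjusted p = 0.0217), while Kdm5d, at -1.5 ± 0.91 (adjusted p = 0.208), and Eif2s3y, at 0.55 ± 0.45 (adjusted p = 0.35), did not pass. Uty was dim, with intensities of 3.83 to 40.4 in ICSI-KSOMaa and 49.2 to 90.7 in vivo. This comparison crosses the sets of arrays, so the share of male embryos cannot be read from Uty. Within the IVF group, replicate 3 had the highest Xist (6468) and the lowest Eif2s3y (628), Kdm5d (8.945) and Uty (34.57). In vivo replicate 4, by contrast, had the lowest Xist (1735) together with the lowest Eif2s3y (232.2) and Kdm5d (66.05) of its group. Males were not counted, so an unequal share of them between the pools of a group stays open.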

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

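The tests of the technical difference between the sets of arrays and of dim probe sets, and the comparison with random lists for all lists but oxidative phosphorylation in ICSI-WM against in vivo, were chosen after the result was seen. In the first pattern, the calls of the 3 comparisons across the sets, all 9 hybridisation control probe sets, which no embryo supplies, separated the sets, so a technical difference is there, and batch and an effect of ICSI cannot be told apart. Without genes below the median intensity, 48.9% of the number of genes lower and 103% of the number higher in ICSI-WM than in vivo were left, but the mean used for this moves with the change itself, so dim probe sets near background stay open for both. Among 10000 random lists matched on intensity, oxidative phosphorylation lay at percentile 100 in the 3 comparisons, p53 targets at 99.63 (ICSI-WM) and 99.87 (ICSI-KSOMaa), and for ICSI-KSOMaa fatty acid oxidation at 99.97, cholesterol biosynthesis at 99.48 and ATF4 targets at 99.11, which argues against a difference that depends on intensity alone as their whole source. Such a difference stays open for apoptosis (94.68 and 91.49), the TCA cycle (97.4) and sperm transcripts (82.82), which lay within the central 95%. The percentiles do not allow for correlation between the members of a list, and with an estimated correlation none of these lists passed. The matching also used the mean that moves with the change, which limits this test. Other splits of the 8 arrays called at most 8, 4 and 1 genes against 5238, 5500 and 4692 (1 split of 35 each, the real one). This argues against chance for the gene counts, though 1 of 35 is the smallest share this test can give. Chance is not excluded for the list counts, which were 3, 8 and 1 against up to 9, 12 and 5 (25, 12 and 29 splits with as many).

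The rise of p53 targets in IVF against in vivo embryos, within a set, is the second pattern. Leaving out each of the 8 arrays gave a lowest list median of 0.754, which argues against a single array as its source. Of the 3 arrays of high 3' to 5' ratio only in vivo replicate 4 belongs to this comparison, so leaving them out (median 0.823) repeats 1 of these fits. It argues against the high ratio of that array as the source. IVF replicate 1, with a b-actin log2 ratio of 2.11, was kept, so RNA quality beyond that array was not tested. The camera p was 7.71e-14 against 7.02e-09 for the smallest of the other splits (1 of 35, the real one), and 26 genes were called against at most 12 (1 of 35). The count of genes argues against chance, but 1 of 35 is the smallest share this test can give. The p53 list was tested because it was called in these arrays, so its p cannot decide on chance. Chance is therefore not excluded for the genes or for the p53 list. The 26 calls used the spread of all 16 arrays, and with the 8 arrays alone no gene passed. Chance is not excluded for the 5 lists called against up to 12 (16 of 35). A response to fertilization and culture outside the mother may account for the rise of p53 targets, as a hypothesis that was not tested. A difference in day or handling between these pools was not recorded and stays open.

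The lower amino acid response and inner cell mass lists in WM against KSOMaa are the third pattern. Without the 3 arrays of high 3' to 5' ratio the median of the ATF4 targets was -0.588, which argues against RNA quality as measured by that ratio. By exact permutation of the arrays into other splits, chance is not excluded for this list (camera p = 1.02e-11 against 2.29e-17 for the smallest of the other splits, with 3 of 35 as small) or for primitive endoderm (1.61e-08 against 6.85e-09, with 3 of 35). For epiblast genes the real split alone gave so small a p (5.74e-06 against 9.46e-05, 1 of 35). That is the smallest share this test can give, and the 3 lists were tested because they were called in these arrays. Chance is therefore not excluded for epiblast genes either, nor for the count of 5 lists (up to 6, with 7 of 35). The 0 genes called by limma, of 567 at an unadjusted p under 0.05, are matched by any split (35 of 35, up to 5), so that count tests nothing. An effect of the medium is not shown for any of these lists. For the epiblast list, Nanog (-0.11 ± 0.17) and Pou5f1 (-0.02 ± 0.29) lay near 0. Its call was lost with an estimated correlation (camera adjusted p = 0.0546) and with fry (adjusted p = 0.0598).

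Single arrays stood far from the other 3 of their group in 14 of 271 gene groups, where chance gives 13.6, and in 2 of 16 groups of array measures, where chance gives 0.8. The Gapdh 3' to 5' log2 ratio was 1.95 on in vivo replicate 4 (others 0.801 to 0.926) and 1.33 on ICSI-WM replicate 4 (others 0.917 to 0.973). High log2 intensities were 7.73 for Gata4 and 4.90 for Zfp688 on in vivo replicate 1, and 13.2 for Hmgcs1 and 9.91 for Hspa1b on IVF replicate 3. Low log2 intensities were 11.2 for Trp53inp1 on in vivo replicate 1, 10.2 for Atf4 on in vivo replicate 3, 5.81 for Aqp3 and 5.55 for Trib3 on IVF replicate 4, 11.9 for Ccng1 and 6.62 for Serpinh1 on ICSI-WM replicate 3, and 7.61 for Snhg3 on ICSI-WM replicate 2. On ICSI-KSOMaa arrays they were 3.19 for Nr0b1 on replicate 2, 6.73 for Slc7a3 on replicate 3 and 10.2 for Gata6 on replicate 4. Of 6912 probe sets without 1 gene symbol, which the comparisons did not use, 2936 were called in ICSI-WM against in vivo (266 higher and 2670 lower), 3055 in ICSI-KSOMaa against in vivo (282 and 2773), 2987 in ICSI-WM against IVF (198 and 2789) and 1, higher, in IVF against in vivo. Limma called 0 of them in ICSI-WM against ICSI-KSOMaa, with 346 at an unadjusted p under 0.05.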

How the results depend on the processing

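Leaving out 3 arrays with high 3' to 5' ratios, joining quantile normalization with the filter at the median intensity, and for lists the 8 arrays alone, other filters, probe set rules and floors were chosen after seeing the data. The cause of the changes below was not tested, except that a filter, or 8 arrays alone, leaves fewer genes or arrays. Dim probe sets limit the falls on ICSI arrays, where 8.31% to 11.9% of probe sets lay under the floor.

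For ICSI-WM against in vivo, ICSI-KSOMaa against in vivo and ICSI-WM against IVF, in that order, centring on the median gave 7899, 7767 and 8019 higher and 889, 998 and 888 lower genes. Quantile normalization gave 1296, 1443 and 1107 lower, the filter at the median 1405, 1516 and 1285, both together 1116, 1254 and 963, and probe sets tested singly 7881, 8177 and 7679. Singly, 3723 and 2980 were higher in the last comparisons, and the mean of probe sets gave 1569 higher in the first. Lists called, from 3, 8 and 1, became 17, 19 and 20 with centring, 10, 14 and 14 with no filter, 19, 18 and 15 with fry and 0, 0 and 0 with an estimated correlation (main calls by camera). They became 6 and 4 with the median filter in the first comparisons, 4 and 2 with quantile normalization in the last, 3 and 2 with both together, and for ICSI-WM against IVF 4 with the mean of probe sets and 4 with a floor of 16. Leaving out arrays gave 1 to 2 lists for ICSI-WM against IVF, with 2 without ICSI-WM replicate 1, 2 or 3.

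For IVF against in vivo the 20 higher and 6 lower genes became 54 and 36 with quantile normalization, 1 and 2 with centring, 65 and 39 with the median filter, 83 and 52 with quantile normalization and that filter, 10 and 2 with array weights, 94 and 62 with a variance trend, 78 and 56 with a floor of 16 and 40 and 25 without the 3 arrays. The mean of probe sets gave 12 higher, and the 8 arrays alone 0 and 0 (limma, 923 at an unadjusted p under 0.05). Leaving out arrays gave 10 (IVF replicate 2) to 78 (in vivo replicate 4) higher and 5 to 53 (in vivo replicate 4) lower, with 36 and 14 without in vivo replicate 3, 32 higher without in vivo replicate 2 and 13 without IVF replicate 3. Lists, from 5, became 3 with the mean of probe sets, 9 without the 3 arrays, 2 with an estimated correlation, 2 with fry, and 3 (without in vivo replicate 2) to 9 (without in vivo replicate 4).

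The replicate number was not used to pair arrays, since nothing in the labels says that it marks a shared day or batch. Same-number correlations were -0.05 to 0.11. For ICSI-WM against in vivo 3 of 4 arrays correlated best with their own number, between the media 2 of 4, and in the other comparisons 0. As a block the replicate number gave 13 higher and 2 lower genes for IVF against in vivo, and 15 genes shared with ICSI-WM.

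For ICSI-WM against ICSI-KSOMaa, higher genes became 1 with quantile normalization, 1 with centring and 2 with array weights, and lower genes 3 with array weights and 1 without the 3 arrays; leaving out arrays gave 0 to 1 higher (1 without ICSI-WM replicate 2) and 0 to 1 lower (1 without ICSI-WM replicate 3), where limma called 0 with 567 at an unadjusted p under 0.05. Lists, from 5, became 3 with quantile normalization, 9 with a floor of 16, 0 with an estimated correlation and 0 with fry.

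Genes shared by the ICSI groups against in vivo, 4373, became 7936 with centring and 9272 with probe sets singly. Those shared by IVF with ICSI-WM and with ICSI-KSOMaa, 23 and 22, became 59 and 58 with quantile normalization, 2 and 2 with centring, 81 and 76 with the median filter, 92 and 90 with both quantile normalization and filter, 0 and 0 with 8 arrays, 11 and 10 with array weights, 110 and 112 with a variance trend, 95 and 89 with a floor of 16 and 44 and 44 without the 3 arrays. The mean of probe sets gave 15 with ICSI-WM. Leaving out an in vivo array gave 27 to 95 and 26 to 92, the highest without in vivo replicate 4, with 42 and 41 without in vivo replicate 3 and 35 for ICSI-WM without in vivo replicate 2. These overlaps were not counted without an IVF or ICSI array, so a lower count there stays open. Those shared by the fertilization and medium comparisons, 0, became 3 with array weights and 1 without the 3 arrays, and 0 to 1 when an ICSI-WM array was left out (1 without ICSI-WM replicate 3). They were not counted without an IVF or ICSI-KSOMaa array.

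Directions turned with centring for Cdx2 (0.52, 0.65 and 0.50 in the 3 comparisons across sets), Nanog (0.17, 0.27 and 0.0935), Slc2a3 (0.56, 0.63 and 0.64) and Dnmt3b (0.50, 0.71 and 0.68), for Dnmt1 against in vivo (0.86) and IVF (0.83), and for Igf2r in ICSI-KSOMaa (0.79). With the mean of probe sets they turned for Dnmt3b in ICSI-KSOMaa (0.035) and, for ICSI-WM against IVF, for Cdx2 (0.0326), Igf2 (-0.67) and Dnmt1 (0.17). No list call turned its direction under the settings run.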

Other observations

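The tests of inner cell mass share and of a response shared by the WM cultures were chosen after the list results were seen. Inner cell mass genes (46 members of the epiblast and primitive endoderm lists) were set against 25 trophectoderm genes as a difference of mean log2 intensity. The difference was -1.90 ± 0.25 (SD, n = 4) in IVF and -1.23 ± 0.19 in vivo embryos, a change of -0.669, with trophectoderm genes at 0.06 (two-sided exact permutation p = 0.886). It was -1.90 ± 0.03 in ICSI-WM and -1.49 ± 0.12 in ICSI-KSOMaa embryos, a change of -0.409, with trophectoderm genes at -0.04 (exact permutation p = 0.743). Since the score is made of lists already called lower in the same arrays, its fall restates those calls and does not test the share of inner cell mass cells. Nanog (0.11 ± 0.17), Pou5f1 (0.17 ± 0.29) and Gata6 (0.01 ± 0.18) were not lower in IVF than in vivo, and between the media Nanog was at -0.11 ± 0.17, Pou5f1 at -0.02 ± 0.29 and Gata6 at -0.42 ± 0.18, none past the threshold. A lower share of these cells and lower expression within them both stay open, and cells were not counted.

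The epiblast, primitive endoderm and ATF4 lists, 3 of 36, were called lower both in IVF against in vivo and in ICSI-WM against ICSI-KSOMaa. Other splits of the arrays called as many lists in either comparison (16 and 7 of 35), so this overlap does not test a response shared by the WM cultures. Across all genes, which are not independent replicates, the changes correlated at 0.0443, and 8 of 100 pairs of other splits gave a correlation as large, up to 0.0602, so the genes do not decide it.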
